A study of Arabidopsis thaliana with 18 samples.

How the data were processed

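The samples were freshly harvested Arabidopsis seeds of Col-0, mkk3-1 and mpk7_ko3, dry or imbibed for 6 h, with 3 libraries in each of 6 groups. Per the labels, total RNA was sequenced as paired reads. The deposited table holds raw counts per gene and library; the processing notes of the authors name fastp 0.20.0, HISAT2 2.1.0, featureCounts 2.0.1, DESeq2 1.34.0 and the TAIR10 genome. Its deposited Length column gives the merged exon length of each gene in bases. Strand setting, treatment of reads with several matches and whether reads or pairs were counted are not stated. Library totals ran from 18249333 to 21036275 counts, and the common biological coefficient of variation between replicates was 0.104.

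Genes with low counts were removed with filterByExpr (minimum count 10), which kept 17758 of 32833 genes. The 15075 genes removed held 0.0393% of counts, and 7726 of them had no read in any library. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with a mean per group over all 18 libraries, which leaves 12 residual degrees of freedom. The 11 comparisons were imbibed against dry seeds in each genotype, each mutant against Col-0 in each state, the mutants against each other in each state, and the difference of each mutant's imbibition response from that of Col-0. P-values were two-sided and adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the edgeR test, as the absolute log2 fold change over the square root of its F statistic. They carry no meaning for genes without reads in a group. CPM were scaled with the TMM factors. A prior count of 2 was used for log2 CPM. For genes without reads in a group, folds were computed against a floor of 3 counts per library, and ratios on few counts carry a 95% counting interval.

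The 28 gene lists were expansins; xyloglucan and mannan remodelling; abscisic acid biosynthesis, catabolism, receptors, clade A PP2C phosphatases, and kinases and transcription factors; gibberellin biosynthesis, inactivation and signalling; dormancy regulators; ethylene pathway and ERF factors; the MKK3 module; other MAPK pathway genes; nitrate response; seed storage proteins and oleosins; LEA proteins and dehydrins; heat shock proteins and factors; cytosolic ribosomal proteins; ribosome biogenesis; lipid mobilisation and glyoxylate cycle; cell cycle and DNA replication; jasmonate pathway; rapid stress response; circadian clock; and markers of seed coat, endosperm and green tissue. Of their members, 387 were matched by locus and symbol and 32 by locus alone. Members removed by the low-count filter were not tested, and all list counts below are of measured members. Measured were, for example, 13 of 25 expansins, 3 of 7 gibberellin inactivation genes and 9 of 14 MKK3 module genes. Of the seed coat and endosperm markers, 10 of 20 and 4 of 12 were measured. Lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01 and adjusted over the lists of a comparison. They were also tested with an estimated correlation and with fry.

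MKK3 and MPK7 were named in every comparison. For imbibition in Col-0 and each mutant against Col-0 in each state, the 8 largest rises and 8 largest falls could be named among genes past the threshold with a mean of at least 5 CPM and no overlap between the library values of the groups. Other comparisons had up to 5 each way. From each list described, up to 4 members past the threshold with the largest change could be named, or up to 2 of the most abundant where none passed. EXPA1, EXPA2, DOG1, CYP707A2, NCED6, NCED9, GA3OX1, GA3OX2 and ERF4 could be named anywhere. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

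Alternatives were DESeq2 1.42.0 (Wald test), its size factors in edgeR, upper-quartile factors, library totals, no low-count filter, nuclear genes only, a fit of only the libraries compared, the replicate number as a block, alone or nested in genotype, an adjusted p below 0.01, a change of at least 2-fold (log2 of 1) and each library left out in turn. Chosen after seeing the data were removal of the GC and length trend of each library, removal of ribosomal RNA genes, leaving out replicate 3 of mpk7_ko3 in both states, and leaving out each library for the gene lists. The fit was tested on simulated data with 200 changed genes, drawn from those with a mean of at least 5 CPM. In imbibed mkk3-1 and the mkk3-1 interaction, 2-fold changes were recovered for 97.0% and 89.6% of genes, and 1.5-fold changes for 77.6% and 47.8%. These shares do not cover genes with lower counts. False calls made up 5.18% and 4.24% of calls in these 2 comparisons. Over all comparisons simulated they ran from 3.11% in the mpk7_ko3 interaction to 7.14% in Col-0 imbibition. Among 20 simulated lists of 20 genes, camera called 10 of 10 shifted by 1.3-fold and 0 of the others. The simulated genes varied independently of each other. In imbibed mkk3-1 the estimated correlation was 0.264 for heat shock genes and 0.555 for ribosomal protein genes. The simulation therefore cannot show how often camera with the preset correlation calls such correlated lists falsely. No library was left out of the fit. Splicing and isoforms were not examined, since the counts are per gene.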

Results

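RNA sequencing counted transcripts in Arabidopsis thaliana seeds of the wild type Col-0 and of 2 mutants, mkk3-1 and mpk7_ko3, in the dry state and after 6 h of imbibition. MKK3 is a mitogen-activated protein kinase kinase and MPK7 a mitogen-activated protein kinase that MKK3 can activate. The labels describe freshly harvested seeds. Each of the 6 groups had 3 libraries, 18 in all, with 18249333 to 21036275 counts per library. The labels do not say whether the replicates are separate seed batches, so they may be technical. Between libraries of a group the chi-square per degree of freedom was 7.06 to 33.2, above counting noise, which argues against repeat runs of 1 library. Of 32833 genes in the count table, 17758 were tested. Fold changes below are log2 values from edgeR ± SE derived from its F statistic, with n = 3 libraries per group. Levels are CPM, counts scaled to the library size, given as means ± SD. A gene rose, fell or changed where its adjusted p was below 0.05. Strand setting and the handling of reads that match several genes are not stated, so counts of paralogs, antisense neighbours and overlapping genes may share reads.

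The main axis of variation between libraries, with 78.9% of the variance in a principal component analysis, parted dry from imbibed seeds. On the axis with 3.95%, replicate 3 of mpk7_ko3 lay apart from the other 2 libraries of its group in both states. The axis with 2.57% parted Col-0 from both mutants. The 10 most abundant genes held 16.5%, 15.5% and 16.2% of counts in dry Col-0, mkk3-1 and mpk7_ko3 seeds, and 12.7%, 13.0% and 14.7% after imbibition. Ribosomal RNA genes held 1.05%, 0.917% and 0.557% in dry seeds and 0.315%, 0.318% and 0.206% in imbibed seeds, in the same order of genotypes.

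The MKK3 transcript (AT5G40440, TAIR10 chromosome 5, 16181628 to 16184827) was lower in dry seeds of mkk3-1, at 7.36 ± 0.342 CPM against 17.38 ± 1.20 CPM in Col-0, a log2 difference of -1.24 ± 0.106 (adjusted p = 4.43e-07). In imbibed seeds labelled mkk3-1 it stood at 11.8 ± 1.29 CPM against 13.3 ± 0.816 CPM, a difference of -0.18 ± 0.0976 that did not pass the test (adjusted p = 0.307). The change of this difference from dry to imbibed seeds was itself past the test, at 1.06 ± 0.144 (adjusted p = 0.0017). The MPK7 transcript (AT2G18170) fell in mpk7_ko3 in both states, by 1.49 ± 0.0951 in dry seeds, from 41.3 to 14.7 CPM, and by 1.45 ± 0.0917 in imbibed seeds, from 35.2 to 12.9 CPM (adjusted p = 1.32e-08 and 1.13e-08). Library values of MKK3 were 7.12, 7.21 and 7.75 CPM in dry mkk3-1, 12.7, 12.3 and 10.3 CPM in imbibed mkk3-1, and between 12.5 and 21.4 CPM in the Col-0 and mpk7_ko3 libraries. MPK7 lay between 11.3 and 15.2 CPM in the mpk7_ko3 libraries and between 32.3 and 44.2 CPM in all others. The end of MKK3 overlaps the gene AT5G40450 on the other strand, and counts per gene cannot tell transcripts of a mutant allele from normal ones.

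**Figure D1:**
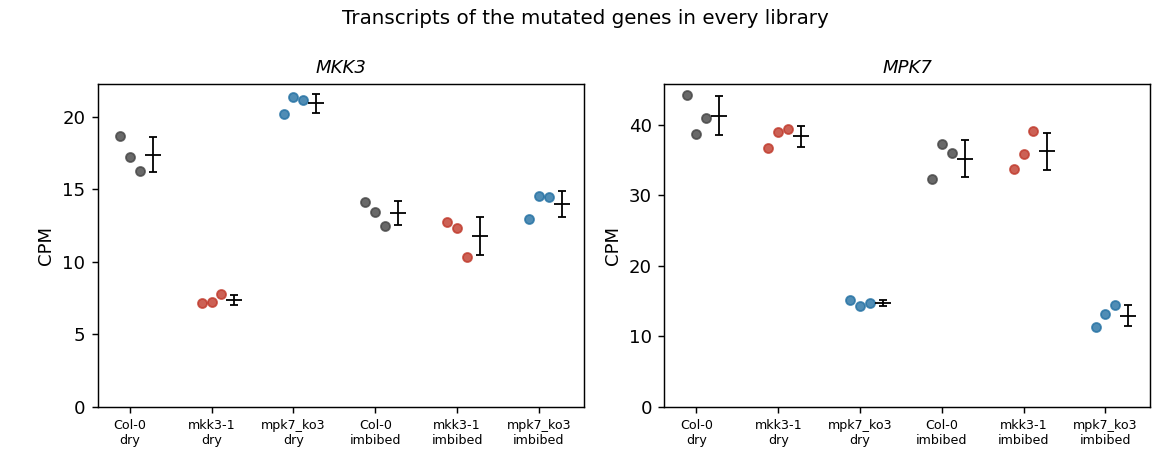
CPM of MKK3 and MPK7 (vertical axes, from 0) in the 18 libraries by group; points are libraries and the black marks are the mean ± SD of 3. MKK3 is low in dry mkk3-1 (7.36 CPM) but not in imbibed mkk3-1 (11.8 CPM), and MPK7 is low in mpk7_ko3 in both states (14.7 and 12.9 CPM).

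Imbibed and dry Col-0 seeds were compared to ask which transcripts change in the first hours of water uptake. All measured ribosomal protein and ribosome biogenesis genes rose and all storage protein genes fell. Of the 28 lists, 11 passed camera with the preset correlation and 0 with an estimated one. EXPA1 (AT1G69530), an expansin that loosens cell walls, rose by 6.28 ± 0.547, from 0.628 to 51.5 ± 12.3 CPM (adjusted p = 1.46e-09). DOG1 (AT5G45830), a main regulator of seed dormancy, fell by 2.27 ± 0.162, from 53.9 ± 15.2 to 11.1 ± 0.199 CPM (adjusted p = 5.99e-11). GA3OX1 and GA3OX2, which catalyse the last step to active gibberellin, had no read in the dry libraries and reached 2.69 ± 0.710 and 4.12 ± 1.02 CPM, at least 14.0-fold and 21.5-fold higher against a floor of 3 counts per library. Such floors and all counting intervals cover counting error only. In all, 6891 genes rose and 6407 fell (51.8% of changed genes higher). Library totals in place of TMM scaling moved the median of all genes from 0.0641 to 0.659 and the share higher to 75.9%, and upper-quartile scaling gave 0.223 and 58.9%. Changes are therefore relative to the scaling. Among the changed genes, 13007 had no overlap between the library values of the groups, as had 78.7% of all genes tested, where chance gives 10%.

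All 22 measured cytosolic ribosomal protein genes rose on imbibition of Col-0 (median 1.335, camera adjusted p = 5.66e-15; adjusted p = 0.239 with an estimated correlation). RPS6A rose by 2.71, from 75.8 to 495 CPM, and RPS5B, RPL4D and RPL23AA by 1.95, 1.74 and 1.74. All 20 ribosome biogenesis genes rose as well (median 1.17, adjusted p = 5.81e-11; adjusted p = 0.239 with an estimated correlation), among them FIB2, the nucleolar protein fibrillarin, by 2.63, NOP5-1 by 2.202 and BOP1 by 2.03. Of 16 cell cycle and DNA replication genes, 11 rose and 0 fell by edgeR (median 1.99, adjusted p = 0.00671; adjusted p = 0.239 with an estimated correlation and 0.0679 with library totals), led by the replication licensing genes MCM7, MCM2 and MCM3 at 5.40, 4.78 and 4.75. LEA proteins and dehydrins, which protect the dry embryo, fell in 15 of 16 cases and rose in 1 (median -1.97, adjusted p = 4.90e-08; adjusted p = 0.291 with an estimated correlation). LEA76 fell by 3.51, from 12110 to 1060 CPM, RAB18 by 2.97 and EM6 by 2.88. Of 18 heat shock genes, 15 fell and 1 rose (median -1.57, adjusted p = 2.25e-06; adjusted p = 0.239 with an estimated correlation), including HSP17.6II by 3.28, the seed heat shock factor HSFA9 by 3.18, HSP21 by 2.69 and HSP101 by 2.40. All 12 storage protein and oleosin genes fell (median -1.46, adjusted p = 0.0191; adjusted p = 0.443 with an estimated correlation and 0.0951 with the GC and length trend removed). OLEO4, an oil body protein, fell by 2.24 and the albumin gene SESA5 by 1.90, from 12990 to 3477 CPM.

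Hormone and dormancy genes moved with imbibition of Col-0 too. None of the 9 measured abscisic acid biosynthesis genes rose and 8 fell (median -1.57, adjusted p = 0.0249; adjusted p = 0.291 with an estimated correlation), with NCED3 at -3.82, NCED2 at -2.39, NCED6 at -2.28 and NCED9 at -1.57. Among 9 clade A PP2C phosphatases, the negative regulators of abscisic acid signalling, 6 fell and 2 rose (median -0.995, adjusted p = 0.00671; adjusted p = 0.291 with an estimated correlation). ABI2 fell by 3.90, HAI1 by 3.83 and AHG1 by 1.85, from 911 to 253 CPM. Of 19 dormancy regulators, 14 fell and 4 rose (median -1.01, adjusted p = 0.0249; adjusted p = 0.245 with an estimated correlation), among them RVE2 and RVE1 by 2.02 and 1.98 beside DOG1. Of 20 ethylene pathway and ERF genes, 15 fell and 3 rose (median -0.79, adjusted p = 0.0473; adjusted p = 0.399 with an estimated correlation), including ERF8 at -2.76 and ERF6 at -2.53, while ERF4 fell by 0.80 (adjusted p = 0.00119, but 0.357 with library totals). The ethylene call ended without Col-0 dry replicates 2 and 3 (adjusted p = 0.0511 and 0.0525), without Col-0 imbibed replicate 3 (adjusted p = 0.0562), with library totals (adjusted p = 0.0679) and with the GC and length trend removed (adjusted p = 0.0667). Of 15 rapid stress response genes, 7 fell and 2 rose (median -0.61, adjusted p = 0.00531; adjusted p = 0.385 with an estimated correlation). The zinc finger gene ZAT6 fell by 5.06, from 125 to 3.74 CPM, DREB2A by 3.38 and WRKY33 by 3.12.

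The other 17 lists did not pass camera in Col-0 imbibition, the lowest adjusted p being 0.0982, though many of their members changed. Of 13 expansins, 8 rose and 3 fell (median 2.302, adjusted p = 0.169), with EXPA10 at 5.28, EXPA9 at 4.90 and EXPA2 at 3.25. Of 14 xyloglucan and mannan remodelling genes, 9 rose and 2 fell (median 1.71, adjusted p = 0.311), XTH9 by 4.68, and XTH16 stood 333 times higher (95% counting interval 59.6 to 13200). Among 10 gibberellin biosynthesis genes, 6 rose and 1 fell (median 0.90, adjusted p = 0.0982), GA20OX2 by 3.65 and GA20OX3 by 3.25. The 3 measured of 7 gibberellin inactivation genes had 2 falls, GA2OX6 at -3.47 and GA2OX2 at -1.89, and 1 rise (adjusted p = 0.311). Of 9 gibberellin signalling genes, 5 rose and 3 fell (median 0.91, adjusted p = 0.17), and the DELLA repressor genes RGA, RGL2 and GAI were among the rises at 2.80, 2.11 and 1.36. Of 9 abscisic acid receptor genes, 7 rose and 2 fell (median 0.98, adjusted p = 0.167), PYL4 by 5.67 from 0.964 to 50.0 CPM. Among the 3 abscisic acid catabolism genes, CYP707A3 rose by 1.12, CYP707A1 fell by 1.74, and CYP707A2 stood at -0.22 (adjusted p = 0.183; without Col-0 dry replicate 2 at -0.42, adjusted p = 0.00894). The list median of -0.22 became 0.38 with library totals (camera adjusted p = 0.806 with TMM).

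Several list medians in Col-0 imbibition changed sign with library totals in place of TMM, and none of these lists passed camera with TMM. The 9 abscisic acid kinases and transcription factors, with 2 rises and 6 falls, went from -0.46 to 0.14 (adjusted p = 0.747), and ABI4 rose by 2.54 while ABI5 fell by 1.96. The 9 measured of 14 genes of the MKK3 module, with 2 rises and 5 falls, went from -0.38 to 0.22 (adjusted p = 0.259). MAPKKK14 and MAPKKK13, kinases upstream of MKK3, fell by 4.34 and 3.09, while MKK3 and MPK7, at -0.38 ± 0.0982 and -0.23 ± 0.0874 (adjusted p = 0.0016 and 0.0234), turned to 0.22 and 0.37 with library totals. The MPK7 call ended without Col-0 dry replicate 1 (-0.18, adjusted p = 0.0995) and without Col-0 imbibed replicate 1 (-0.17, adjusted p = 0.125). The 11 circadian clock genes, with 2 rises and 7 falls, went from -0.50 to 0.095 (adjusted p = 0.265), and LHY rose by 2.48. The 12 nitrate response genes, with 3 rises and 6 falls, went from -0.16 to 0.41 (adjusted p = 0.832, mean 0.036, tested direction upward), NRT1.1 rising by 2.27 and NIR1 falling by 2.01. The 15 lipid mobilisation genes, with 7 rises and 6 falls, had a median of 0.0038 and of -0.025 with DESeq2 size factors (adjusted p = 0.806), PCK1 rising by 1.04. The 10 other MAPK pathway genes, with 2 rises and 2 falls, had a median of 0.025, a mean of 0.36 and a downward test (adjusted p = 0.806), and -0.0041 with DESeq2 size factors. MPK3 fell by 1.35.

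The remaining lists of Col-0 imbibition were the jasmonate pathway and markers of other tissues. Of 15 jasmonate genes, 11 fell and 3 rose (median -0.98, adjusted p = 0.0982, and 0.0365 with library totals), AOC2 by 3.18 and the repressor JAZ10 by 2.70. Among 10 seed coat markers, 4 rose and 2 fell (median 0.28, mean -0.010, tested direction upward, adjusted p = 0.518), with PER36 at -4.26 and CESA5 at 1.76. Among 4 endosperm markers, 2 fell and 1 rose (median -1.04, adjusted p = 0.143), EPR1 (AT2G27380) by 1.74, from 20110 to 6031 CPM. Among 13 green tissue markers, 5 rose and 4 fell (median 0.68, adjusted p = 0.842), RBCS3B by 4.18 upward and LHCB5 by 3.64 downward. Adjusted over the list alone, counts were those over all genes except 1 rise and 2 falls of other MAPK genes and 4 rises and 1 fall of seed coat markers. The largest changes outside the lists were rises of the homeobox gene WOX11 by 7.25 ± 0.296 (adjusted p = 1.20e-14), bZIP44 by 6.97 and the NAC gene NTL8 by 6.43. Falls were led by AT4G11911, annotated as STAY-GREEN-like, at -6.18 ± 0.143 (adjusted p = 1.28e-17), and SIS at -5.46, from 516 to 11.7 CPM.

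**Figure D2:**
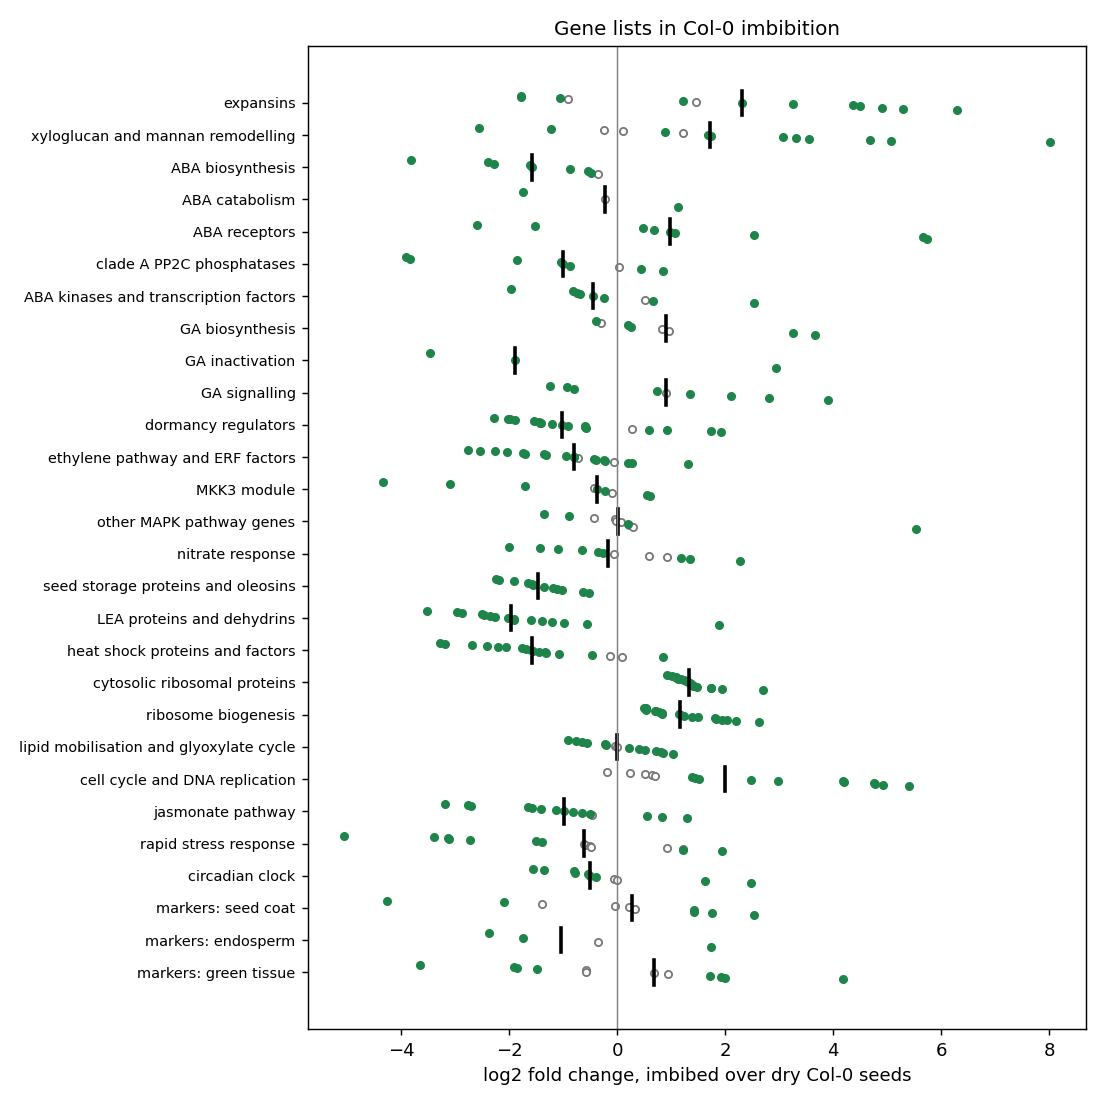
Log2 fold change of imbibed over dry Col-0 seeds (horizontal axis) for the measured members of the 28 gene lists; filled points passed the test, open points did not, and the black bar is the list median. GA3OX1, GA3OX2 and RBCS2B, with no read in dry seeds, are in the medians but not drawn. All 22 ribosomal protein genes lie to the right of 0 and all 12 storage protein genes to the left; with library totals all genes shift by their median of 0.659 in place of 0.0641, and the medians of 5 lists drawn left of 0 move to the right.

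The same comparison within each mutant asks how far the imbibition response is kept. EXPA1 and WOX11 rose by 6.98 and 6.81 in mkk3-1, and WOX11 rose by 6.604 in mpk7_ko3, where EXPA10 rose by 6.73. The EXPA1 fold rests on 1 to 4 counts per library in dry mkk3-1 (0.137 ± 0.0871 CPM). Its imbibed level in mkk3-1 was 18.3 CPM, against 51.5 CPM in imbibed Col-0. EXPA10 was likewise lower in imbibed mpk7_ko3 than in imbibed Col-0. A large fold from a low dry level is therefore no sign of a stronger response. DOG1 fell by 1.64 ± 0.154 in mkk3-1 and by 1.59 ± 0.153 in mpk7_ko3. Its difference from the Col-0 response did not pass the test in either mutant (0.63 ± 0.221, adjusted p = 0.353, and 0.68 ± 0.220, adjusted p = 0.449). SIS fell by 5.35 and 5.51 and the transporter gene ABCI21 by 5.71 and 5.59. PGA4 was at least 165-fold lower in imbibed than in dry mpk7_ko3, and bZIP44 stood 253 times higher (95% counting interval 69.8 to 2090). In mkk3-1, 6657 genes rose and 6358 fell, and in mpk7_ko3 6684 rose and 6189 fell; without replicate 3 of mpk7_ko3 in both states, a choice made after seeing the data, 12213 genes changed in place of 12873. All 22 ribosomal protein and all 20 ribosome biogenesis genes rose in each mutant, while 13 of 18 heat shock genes and 15 of 16 LEA genes fell in each. Of the 28 lists, 10 passed camera in mkk3-1 and 8 in mpk7_ko3, and 0 in either with an estimated correlation (lowest adjusted p = 0.302), where camera with its preset correlation gave the 10 and 8. Library totals raised the share higher to 75.2% and 75.8%. Library values did not overlap for 76.6% and 72.0% of genes tested, where chance gives 10%. MKK3 rose by 0.68 in mkk3-1 and fell by 0.58 in mpk7_ko3, and MPK7 stood at -0.08 in mkk3-1 (0.47 with library totals) and at -0.19 in mpk7_ko3 (0.37 with library totals; -0.27, adjusted p = 0.0295, without mpk7_ko3 imbibed replicate 3).

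Dry seeds of mkk3-1 were compared with dry Col-0 seeds to ask which stored transcripts depend on MKK3. The heat shock list was higher, with 8 of 18 members past the test. The ribosomal and storage protein lists were lower with the preset correlation, with 3 of 22 and 3 of 12 members past the test, but not with an estimated one (adjusted p = 0.272 and 0.315). By fry, which does not compare a list with other genes, the ribosomal list passed and the storage list did not (adjusted p = 0.0247 and 0.136). HSP21, a plastid chaperone, rose by 2.16 ± 0.279, from 26.9 to 120 CPM (adjusted p = 0.000167), and HSP22 by 1.62 ± 0.176. The uncharacterised gene AT1G64795 (chromosome 1, 24082579 to 24082848) rose by 6.67 ± 0.269, from 4.66 ± 1.54 to 479 ± 84.9 CPM (adjusted p = 1.61e-12), and ILA, on whose opposite strand it lies, by 1.92 ± 0.113. Also higher were AT1G29970, annotated RPL18AA, by 2.83 ± 0.140, IRT3, a metal transporter, by 2.34 and the peptide transporter PTR5 by 1.56. The noncoding RNA AT3G05945 fell by 2.103 ± 0.178, from 112 to 26.0 CPM, AT1G55360 by 2.91, and the DUF642 genes DGR2 and AT1G29980 by 1.97 and 1.58. Among maturation and growth genes, ABI3 fell by 0.39, RGL2 by 0.79, ERF12 by 0.40 and the expansin EXPA3 by 1.22. DOG1 stood at 0.11 ± 0.148 (adjusted p = 0.78) and EXPA1 at -2.19 ± 1.41 (adjusted p = 0.491). GA3OX1 and GA3OX2 had no read in dry seeds of either genotype.

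Of 18 heat shock genes, 8 rose and 0 fell in dry mkk3-1 by edgeR (median 0.43, camera adjusted p = 1.72e-18; adjusted p = 0.0296 with an estimated correlation), and adjusted over the list alone 12 rose and 1 fell. HSP17.6II and HSP17.6B rose by 1.38 and 0.90. None of 22 ribosomal protein genes rose and 3 fell, or 18 adjusted over the list alone (median -0.27, adjusted p = 7.95e-13; adjusted p = 0.272 with an estimated correlation). Of 12 storage protein and oleosin genes, 3 fell, or 7 adjusted over the list alone (median -0.40, adjusted p = 1.70e-06; adjusted p = 0.315 with an estimated correlation). SESA3 fell by 2.09 ± 0.450, from 4145 ± 2237 to 973 CPM, but not past the test without Col-0 dry replicate 1 (-1.56, adjusted p = 0.0877) or mkk3-1 dry replicate 1 (-1.96, adjusted p = 0.104). Gibberellin signalling genes had 3 falls of 9, or 4 adjusted over the list alone (median -0.10, adjusted p = 0.000956; adjusted p = 0.217 with an estimated correlation). The endosperm marker list had 1 fall of 4, or 2 adjusted over the list alone (median -0.40, adjusted p = 0.025; adjusted p = 0.272 with an estimated correlation), but adjusted p = 0.118 without Col-0 dry replicate 1, 0.0555 without mkk3-1 dry replicate 1 and 0.053 with the GC and length trend removed. LEA genes had no single change (median -0.20, adjusted p = 0.0202; adjusted p = 0.775 with an estimated correlation), with 0.201 and 0.165 when the same libraries were left out and 0.0559 with the GC and length trend removed. Lipid mobilisation genes had 1 fall of 15 (median -0.11, adjusted p = 0.0108; adjusted p = 0.67 with an estimated correlation; 0.091 without Col-0 dry replicate 2 and 0.051 with library totals). Clock genes had no single change (median 0.11, adjusted p = 0.0202; adjusted p = 0.28 with an estimated correlation; 0.114 without Col-0 dry replicate 2 and 0.053 with the GC and length trend removed). Rapid stress genes had none either, or 2 rises adjusted over the list alone (median 0.20, adjusted p = 0.0462; adjusted p = 0.67 with an estimated correlation; 0.107, 0.109 and 0.165 without Col-0 dry replicate 1, Col-0 dry replicate 3 and mkk3-1 dry replicate 1, 0.0834 with library totals and 0.0526 with the GC and length trend removed). The other 19 lists did not pass (lowest adjusted p = 0.0957), though expansins did without Col-0 dry replicate 1 (0.0422), without Col-0 dry replicate 3 (0.0216) and with library totals (0.0275).

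In all, 122 genes rose and 248 fell in dry mkk3-1, 33.0% of them higher, against 51.3% with library totals. Of these 366 had no overlap between library values, as had 18.4% of genes tested, where chance gives 10%. Single libraries moved the count of 370 by more than 1.5 times: it was 233 without Col-0 dry replicate 2, 157 without Col-0 dry replicate 3, 130 without mkk3-1 dry replicate 1 and 181 without mkk3-1 dry replicate 3. DESeq2 gave 649 and a fit of only the libraries compared 230.

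Imbibed seeds labelled mkk3-1 were compared with imbibed Col-0 seeds to ask which early responses depend on MKK3. The heat shock list was higher and the expansin list lower, also with an estimated correlation (adjusted p = 0.000765 and 0.0339), and the ribosomal protein list was lower with the preset correlation (adjusted p = 0.0794 with an estimated correlation). The dormancy list did not pass (median 0.013, adjusted p = 0.0947), though 3 of its 19 members rose. EXPA10 fell by 2.38 ± 0.271, from 33.2 to 6.39 CPM (adjusted p = 1.39e-05), and EXPA8 fell by 1.696 ± 0.245. GA3OX2 fell by 2.37 ± 0.429, from 4.12 to 0.794 CPM (adjusted p = 0.00332). DOG1 rose by 0.74 ± 0.164, from 11.1 to 18.7 CPM (adjusted p = 0.00665), RVE1 by 1.12 and RVE2 by 0.51. The imbibition response of DOG1 did not differ from that of Col-0 past the test (0.63, adjusted p = 0.353). HSP21 rose by 3.19 ± 0.326, from 4.18 to 38.3 CPM (adjusted p = 3.68e-06), HSP22 by 1.93 ± 0.177 and HSP17.6II by 1.95. The largest rises were AT1G64795 at 6.87 ± 0.315 and IRT3 at 6.06 ± 0.271, from 0.432 to 29.4 CPM, and the flavonoid gene TT4 rose by 2.32. AT3G05945 fell by 2.15 ± 0.188, DGR2 by 1.63, from 255 to 82.3 CPM, and HEI10 by 1.57.

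In imbibed mkk3-1, 14 of 18 heat shock genes rose and 0 fell by edgeR, 15 and 0 adjusted over the list alone (median 0.80, camera adjusted p = 6.88e-44; adjusted p = 0.000765 with an estimated correlation). None of 13 expansins rose and 5 fell, or 7 with 1 rise adjusted over the list alone (median -1.28, adjusted p = 9.07e-06; adjusted p = 0.0339 with an estimated correlation). EXPA15 fell by 2.07. EXPA1 fell by 1.49 ± 0.344, from 51.5 to 18.3 CPM (adjusted p = 0.00901), but adjusted p was 0.254 by DESeq2, 0.0599 without Col-0 imbibed replicate 3, and 0.0655 and 0.0547 without mkk3-1 imbibed replicates 1 and 2. EXPA2 stood at -1.28 ± 0.647 (adjusted p = 0.262), and was past the test without mkk3-1 imbibed replicate 3 (-2.93, adjusted p = 0.0147) and with a replicate block (-1.73, adjusted p = 0.046). Of 22 ribosomal protein genes, 20 fell, and all 22 adjusted over the list alone (median -0.39, adjusted p = 7.50e-21; adjusted p = 0.0794 with an estimated correlation), with RPL23AA at -0.51, RPL14B at -0.50 and RPL28A at -0.49. Clock genes rose in 5 of 11 cases, also adjusted over the list alone (median 0.29, adjusted p = 0.000292; adjusted p = 0.074 with an estimated correlation), RVE8 by 0.41. Of 12 nitrate response genes 2 rose, NIR1 by 0.94 and NIA1 by 0.68, or 4 adjusted over the list alone (median 0.30, adjusted p = 0.00088; adjusted p = 0.206 with an estimated correlation). Storage protein and oleosin genes fell in 4 of 12 cases on either count (median -0.28, adjusted p = 0.0019; adjusted p = 0.42 with an estimated correlation), SESA3 by 2.21 and OLEO3 by 0.78. Of 4 endosperm markers 2 fell on either count, EPR1 (AT2G27380) among them from 6031 to 3113 CPM (list median -0.55, adjusted p = 0.0233; adjusted p = 0.165 with an estimated correlation).

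The remaining calls in imbibed mkk3-1 ended when single libraries were left out. Gibberellin biosynthesis genes fell in 3 of 10 cases on either count (median -0.42, adjusted p = 0.0387; adjusted p = 0.308 with an estimated correlation), with 0.094 without Col-0 imbibed replicate 1 and 0.0875 and 0.103 without mkk3-1 imbibed replicates 1 and 3. LEA genes fell in 4 of 16 cases, 6 adjusted over the list alone (median -0.28, adjusted p = 0.0238; adjusted p = 0.529 with an estimated correlation), with 0.11 and 0.248 without Col-0 and mkk3-1 imbibed replicate 2. Ribosome biogenesis genes fell in 2 of 20 cases on either count (median -0.15, adjusted p = 0.00429; adjusted p = 0.47 with an estimated correlation; 0.0573 without mkk3-1 imbibed replicate 3). Rapid stress genes rose in 2 of 15 cases, ZAT6 by 0.66 (median 0.34, adjusted p = 0.0223; adjusted p = 0.444 with an estimated correlation; 0.0595 without Col-0 imbibed replicate 1 and 0.162 without mkk3-1 imbibed replicate 3). The other 17 lists did not pass (lowest adjusted p = 0.0576). Of these, xyloglucan and mannan remodelling passed without Col-0 imbibed replicate 1 (0.0299) and mkk3-1 imbibed replicate 3 (0.00683), with the replicate block (0.0375), with library totals (0.0432) and with the GC and length trend removed (0.0379). Abscisic acid biosynthesis passed without Col-0 imbibed replicate 1 or 2 (0.0467 and 0.0453) or mkk3-1 imbibed replicate 2 (0.00825). Gibberellin signalling passed without Col-0 imbibed replicate 1 (0.0409) and other MAPK genes without Col-0 imbibed replicate 3 (0.0387), and both with the GC and length trend removed (0.0444 and 0.0459). By fry xyloglucan and mannan remodelling, abscisic acid biosynthesis, gibberellin signalling and other MAPK genes passed too (adjusted p = 0.0444, 0.046, 0.0284 and 0.0284). Single genes of the other 17 lists that passed included ABA1 at 0.32, AHG3 at -0.50, RGL3 at -0.87, MAPKKK13 at 0.98 and the mannanase MAN7 at -0.78.

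In all, 644 genes rose and 768 fell in imbibed mkk3-1, 45.6% of them higher, and 56.8% with the GC and length trend removed, an alternative chosen after seeing the data. Library values did not overlap for 1405 of these and for 32.7% of genes tested, where chance gives 10%. Each single library moved the count of 1412 by more than 1.5 times except Col-0 imbibed replicate 2. It was 756 and 781 without Col-0 imbibed replicates 1 and 3, and 793, 927 and 839 without mkk3-1 imbibed replicates 1, 2 and 3. A fit of the compared libraries alone gave 2887.

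Dry seeds of mpk7_ko3 were compared with dry Col-0 seeds to ask which stored transcripts depend on MPK7. The ribosomal protein list was lower, with 15 of 22 members past the test, and the heat shock list higher, with 5 of 18, both with the preset correlation but not with an estimated one (adjusted p = 0.13 and 0.405). By fry the ribosomal list passed and the heat shock list did not (adjusted p = 0.00228 and 0.0716). RPL14B fell by 0.59, RPL28A by 0.55, RPS18A by 0.53 and the fibrillarin gene FIB2 by 0.68. HSP21 rose by 1.21 ± 0.279 (adjusted p = 0.0203), with 105 CPM in replicate 3 of mpk7_ko3 against 44.2 and 37.9 CPM in the others; the adjusted p was 0.123 without that library, 0.0805 without Col-0 dry replicate 2 and 0.0867 without Col-0 dry replicate 3. The largest stable rise was AT2G41650, an uncharacterised gene, at 1.21 ± 0.114, from 6.45 to 15.0 CPM (adjusted p = 5.21e-06), and the cell cycle regulator DEL2 rose by 0.97 ± 0.134. Falls beside MPK7 included AT2G01008 at -1.703 ± 0.174, GSTU7 at -1.49, HSD1, an oil body steroleosin, at -1.45, from 224 to 82.2 CPM, and the brassinosteroid gene DWF1 at -1.26. The 18S ribosomal RNA gene AT2G01010 fell by 1.55 ± 0.214, from 99.6 to 34.1 CPM. The share of ribosomal RNA was lower too, but by less, at 0.557% against 1.05% in dry Col-0. In dry Col-0 replicates 1, 2 and 3 it was 0.844%, 1.41% and 0.896%. AT2G01008 (chromosome 2, 1025 to 3173) carries a neighbouring locus number. Whether its fall follows the ribosomal RNA share was not tested. EXPA3 fell by 1.06, and DOG1 stood at 0.24 ± 0.148 (adjusted p = 0.445).

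Of 22 ribosomal protein genes, 15 fell and 0 rose in dry mpk7_ko3 by edgeR, and 21 fell adjusted over the list alone (median -0.39, camera adjusted p = 5.75e-28; adjusted p = 0.13 with an estimated correlation). Heat shock genes rose in 5 of 18 cases, 8 adjusted over the list alone (median 0.29, adjusted p = 1.45e-06; adjusted p = 0.405 with an estimated correlation). Ribosome biogenesis genes fell in 2 of 20 cases on either count (median -0.11, adjusted p = 0.0269; adjusted p = 0.826 with an estimated correlation). Their call ended without Col-0 dry replicate 2 or 3 (0.117 and 0.0926) or mpk7_ko3 dry replicate 1 or 3 (0.129 and 0.197). Gibberellin signalling genes fell in 2 of 9 cases, 3 adjusted over the list alone (median -0.10, adjusted p = 0.0437; adjusted p = 0.54 with an estimated correlation). Among them GAI fell by 0.52, with adjusted p = 0.0567 without Col-0 dry replicate 3. The list call ended without Col-0 dry replicate 1 or 3 (0.132 and 0.0926) or mpk7_ko3 dry replicate 2 or 3 (0.0521 and 0.197). The other 24 lists did not pass (lowest adjusted p = 0.14), but without mpk7_ko3 dry replicate 1 the storage protein, LEA and clock lists did (0.0341, 0.000778 and 0.03), as did lipid mobilisation with the GC and length trend removed (0.0417). In all, 116 genes rose and 375 fell, 24% of them higher, and 37.7% with the GC and length trend removed; 481 of them and 18% of genes tested had no overlap between library values, where chance gives 10%. The count of 491 was 73 in a fit of only the libraries compared, where another split of them gave 175, and 775 by DESeq2. It was 146 without Col-0 dry replicate 2, 262 without Col-0 dry replicate 3 and 271 without mpk7_ko3 dry replicate 2. Without replicate 3 of mpk7_ko3 in both states it was 486.

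Imbibed seeds of mpk7_ko3 were compared with imbibed Col-0 seeds to ask which early responses depend on MPK7. The heat shock list was higher, also with an estimated correlation (adjusted p = 0.00541). The dormancy list was higher and the expansin and ribosomal protein lists lower with the preset correlation but not with an estimated one (adjusted p = 0.0785, 0.248 and 0.0785), and all 3 passed by fry (adjusted p = 0.00117, 0.0218 and 0.000485). DOG1 rose by 0.92 ± 0.163, from 11.1 to 21.1 CPM (adjusted p = 0.00121), and the maturation regulator FUS3 by 0.92 ± 0.175. The imbibition response of DOG1 did not differ from that of Col-0 past the test (0.68, adjusted p = 0.449). HSP21 rose by 2.28 ± 0.332, from 4.18 to 20.4 CPM (adjusted p = 0.000223), HSP22 by 1.48 ± 0.175, HSP17.6B by 1.21 ± 0.110 and Hsp70b by 1.17 ± 0.148, from 564 to 1270 CPM. EXPA10 fell by 1.45 ± 0.257 (adjusted p = 0.00125; by DESeq2 adjusted p = 0.0725) and EXPA15 by 1.85. EXPA1 fell by 1.53 ± 0.345, from 51.5 to 17.79 CPM (adjusted p = 0.00715), but adjusted p was 0.196 by DESeq2 and 0.051 without mpk7_ko3 imbibed replicate 1. GA3OX2 stood at -0.95 ± 0.392 (adjusted p = 0.153), and its difference from imbibed mkk3-1 did not pass the test either (-1.42 ± 0.437, adjusted p = 0.203, but -1.81 and 0.0252 without mpk7_ko3 imbibed replicate 3). Beside MPK7, AT1G49700 fell by 1.97 ± 0.339, AT2G24280 by 1.48 ± 0.115, the nitrate transporter gene NRT2.6 by 1.298 and the microtubule gene MAP65-2 by 1.24.

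Of 18 heat shock genes, 13 rose and 0 fell in imbibed mpk7_ko3 by edgeR, 15 and 1 adjusted over the list alone (median 0.87, camera adjusted p = 2.54e-28; adjusted p = 0.00541 with an estimated correlation). Of 22 ribosomal protein genes 19 fell, 20 adjusted over the list alone (median -0.40, adjusted p = 6.24e-21; adjusted p = 0.0785 with an estimated correlation), with RPL23AA at -0.59 and RPS11A at -0.57. Dormancy regulators rose in 4 of 19 cases, DOG1, FUS3, RVE1 and RVE2, and in 6 adjusted over the list alone (median 0.10, adjusted p = 0.00313; adjusted p = 0.0785 with an estimated correlation). Clock genes rose in 4 of 11 cases, 8 adjusted over the list alone (median 0.37, adjusted p = 5.70e-05; adjusted p = 0.0603 with an estimated correlation), RVE8 by 0.46, PRR7 by 0.39 and GI by 0.37. Expansins fell in 5 of 13 cases, 6 adjusted over the list alone, while the expansin-like EXLA1 rose by 1.02 (median -1.04, adjusted p = 0.0164; adjusted p = 0.248 with an estimated correlation; 0.13 without mpk7_ko3 imbibed replicate 2). Jasmonate genes rose in 4 of 15 cases on either count, JAZ2 by 0.66 and JAZ3 by 0.63 (median 0.22, adjusted p = 0.0333; adjusted p = 0.328 with an estimated correlation). Their call ended without Col-0 imbibed replicate 1 or 2 (0.0588 and 0.154) or mpk7_ko3 imbibed replicate 1 or 3 (0.114 and 0.124), and with the GC and length trend removed (0.0686). Ribosome biogenesis genes fell in 1 of 20 cases, FIB2 by 0.52, and in 3 adjusted over the list alone (median -0.094, adjusted p = 0.0136; adjusted p = 0.633 with an estimated correlation; 0.0796 without mpk7_ko3 imbibed replicate 3). The other 21 lists did not pass camera (lowest adjusted p = 0.142), except lipid mobilisation without mpk7_ko3 imbibed replicate 3 (0.0218). By fry the MKK3 module and other MAPK genes passed too (adjusted p = 0.0218 and 0.0354), but the module holds MPK7 itself. Among members of the other 21 lists MAN7 stood at -0.79, ABA1 at 0.30, OLEO1 at 0.57, MKK5 at 0.30 and RBCS1A at -0.84, all past the test. In all, 909 genes rose and 839 fell, 52.0% of them higher, against 37.6% with library totals and 64.1% with the GC and length trend removed. Library values did not overlap for 1725 of them and for 31.0% of genes tested, where chance gives 10%. The count of 1748 was 1003, 1079 and 896 without Col-0 imbibed replicates 1, 2 and 3, and 887 without mpk7_ko3 imbibed replicate 1. Without replicate 3 of mpk7_ko3 in both states it was 1820.

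**Figure D3:**
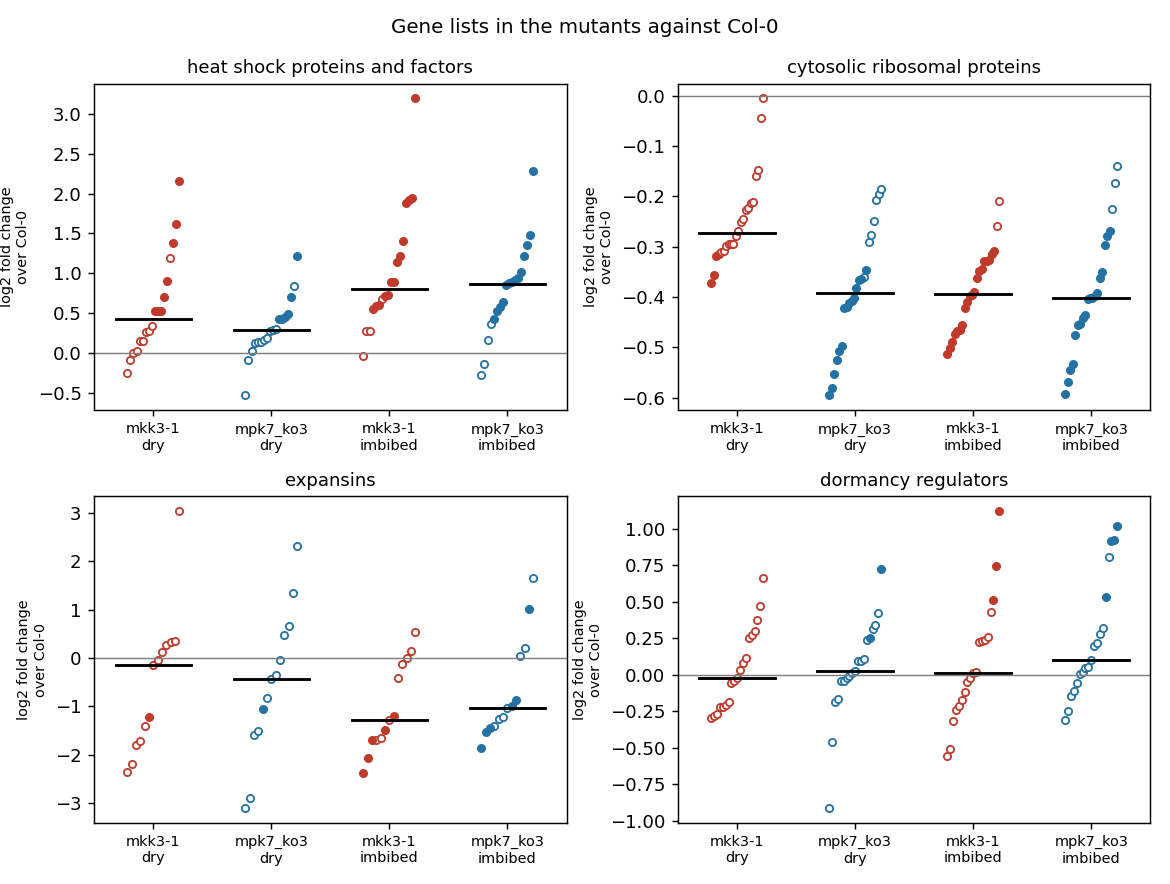
Log2 fold change over Col-0 in the same state (vertical axes) of the measured members of 4 lists in dry and imbibed seeds of each mutant; filled points passed the test, open points did not, and the black bar is the list median. Heat shock medians are 0.43, 0.29, 0.80 and 0.87 from left to right and ribosomal protein medians -0.27, -0.39, -0.39 and -0.40, while the dormancy list median in dry mkk3-1 (-0.024) turns to 0.027 with library totals.

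**Figure D4:**
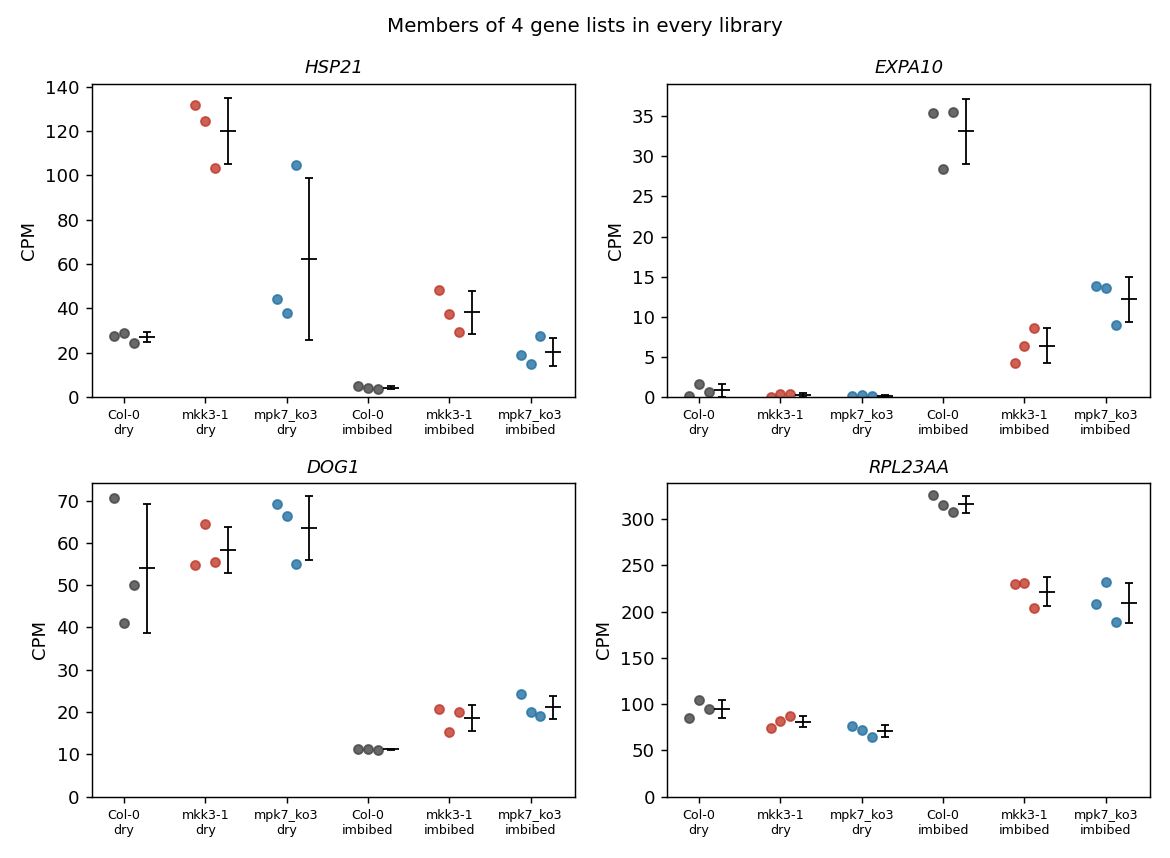
CPM of HSP21, EXPA10, DOG1 and RPL23AA (vertical axes, from 0) in the 18 libraries by group; points are libraries and the black marks are the mean ± SD of 3. In imbibed seeds HSP21 and DOG1 lie higher in both mutants than in Col-0 and EXPA10 and RPL23AA lower, and HSP21 in dry mpk7_ko3 replicate 3 (105 CPM) stands apart from the other libraries of its group (44.2 and 37.9 CPM).

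The mutants shared many of these changes. In imbibed seeds 811 genes changed the same way in both, 375 higher and 436 lower, among them HSP21, HSP22, DOG1, RVE1 and RVE2 on the higher side and EXPA10, EXPA15 and RPL23AA on the lower, and 1 changed in opposite directions. They made up 57.4% of the mkk3-1 and 46.4% of the mpk7_ko3 changes, where independent lists would share 69.3. In dry seeds 115 genes were shared, 25 higher and 90 lower, with 0 in opposite directions among genes past edgeR in both mutants, where independent lists would share 6.03. Both mutants were set against the same 3 Col-0 libraries, so fold changes correlate across genes even without any mutant effect. Across genes, which are not independent replicates, r was 0.63 in imbibed seeds against 0.497 (0.469 to 0.528) in 20 simulations of unchanged mutants, and 0.45 in dry seeds against 0.505 (0.477 to 0.532). The covariance was 0.120 against 0.0404 simulated in imbibed seeds and 0.106 against 0.0602 in dry seeds. The dry r was thus below the simulated range. The simulations hold no changed genes, so they give no number of shared genes to set beside 115 and 811, and how many of these come from the shared Col-0 libraries is not known. The imbibed count was 423 and 405 without Col-0 imbibed replicates 1 and 3 and 523 without mkk3-1 imbibed replicate 3. The dry count was 30 and 36 without Col-0 dry replicates 2 and 3, and 53 and 64 without mkk3-1 dry replicates 1 and 3. Between states, 210 genes changed in both dry and imbibed mkk3-1, 208 of them the same way, and 315 in both states of mpk7_ko3, 312 the same way.

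The mutants were also compared with each other, which leaves the Col-0 libraries out of the contrast. In dry seeds AT1G64795 stood 6.16 ± 0.258 higher in mkk3-1 than in mpk7_ko3, RPL18AA 2.54 and ILA 1.97 higher, and AT3G05945 fell by 2.096 and ZML1 by 1.32. MKK3 itself stood at -1.51 ± 0.105. In imbibed seeds IRT3 stood 5.75 ± 0.262 and MPK7 1.49 ± 0.0916 higher in mkk3-1, AT3G05945 at -2.59 ± 0.188, HEI10 at -1.52 and EPR1 (AT2G27380) at -1.23. In dry seeds 136 genes were higher and 79 lower in mkk3-1, and in imbibed seeds 23 and 37. The share higher was 63.3% in dry seeds, 80.5% with library totals and 43.5% with the GC and length trend removed, and in imbibed seeds 38.3%, 56.6% with library totals and 50.0% with upper-quartile factors. Library values did not overlap for 17.7% of genes tested in either state, where chance gives 10%. Endosperm markers passed in imbibed seeds (median -0.23, camera adjusted p = 4.62e-05, and adjusted p = 0.0167 with an estimated correlation). Of the 12 listed markers only 4 were measured, and 2 of these were lower on either count. The MKK3 module also passed (adjusted p = 0.000148; adjusted p = 0.0167 with an estimated correlation), but it holds MPK7, its only member past the test over all genes, so the mutation in mpk7_ko3 fixes the call in part and it was not tested without MPK7. Storage protein genes had 0 of 12 lower by edgeR and 6 adjusted over the list alone in imbibed seeds (median -0.48, adjusted p = 1.27e-09; adjusted p = 0.219 with an estimated correlation). The other 5 lists past the preset correlation in imbibed seeds and all 5 in dry seeds were lost with an estimated one (lowest adjusted p = 0.219 and 0.532).

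Both counts between the mutants depended on the method and on single libraries. DESeq2 gave 610 in dry and 226 in imbibed seeds, and the fit without the low-count filter 504 and 233. A fit of only the libraries compared gave 29 in dry seeds, where another split of them gave 298, and the GC and length trend removed gave 105 in imbibed seeds. The dry count of 215 was 40 and 85 without mkk3-1 dry replicates 1 and 3, and 127, 33 and 882 without mpk7_ko3 dry replicates 1, 2 and 3. The imbibed count of 60 was 22 and 24 without mkk3-1 imbibed replicates 1 and 2, and 18, 32 and 198 without mpk7_ko3 imbibed replicates 1, 2 and 3. Without replicate 3 of mpk7_ko3 in both states they were 1095 and 454.

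The interaction asks whether a gene responds to imbibition differently in a mutant than in Col-0. In mkk3-1, IRT3 fell by 1.52 in Col-0 and rose by 2.21 in the mutant, a difference of 3.73 ± 0.428 (adjusted p = 0.000224), and MKK3 differed by 1.06 ± 0.144 (adjusted p = 0.0017). ILA rose by 1.336 in Col-0 and fell by 0.58 in the mutant, a difference of -1.92 ± 0.155 (adjusted p = 9.93e-07). RPL18AA differed by -1.53 ± 0.192, and the sulfate assimilation gene APR2 by -0.95. In mpk7_ko3, AT2G41650 rose by 2.83 in Col-0 and by 0.85 in the mutant, a difference of -1.98 ± 0.147 (adjusted p = 2.14e-07). In all 22 genes differed in mkk3-1, 14 with a higher and 8 with a lower response (50.0% higher with library totals against 63.6%), and 1 in mpk7_ko3. At an unadjusted p below 0.05 there were 1562 and 1361 of 17758 genes, where a share of 0.05 is due without any effect. DESeq2 gave 161 and 58. Without the low-count filter there were 90 and 36, with the GC and length trend removed 44 and 4, and a fit of only the libraries compared gave 97 in mkk3-1. With the replicate number nested in genotype as a block, 63 and 22 genes differed. The count of 22 was 7, 9, 7 and 8 without Col-0 dry replicate 3 and Col-0 imbibed replicates 1, 2 and 3, and 9, 78 and 10 without mkk3-1 dry replicates 1, 2 and 3. It was 5, 11 and 11 without mkk3-1 imbibed replicates 1, 2 and 3. The count of 1 was 2 without Col-0 dry replicate 1, Col-0 dry replicate 3 or mpk7_ko3 imbibed replicate 3, 3 without mpk7_ko3 imbibed replicate 1 and 19 without mpk7_ko3 dry replicate 3. Heat shock genes had no single interaction past edgeR in either mutant, but 9 and 12 of 18 adjusted over the list alone (camera adjusted p = 2.82e-12 and 6.58e-15; adjusted p = 0.136 and 0.0709 with an estimated correlation). The other 4 lists past the preset correlation in each mutant were lost with an estimated one too (lowest adjusted p = 0.499).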

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

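All tests of explanations in this part were chosen after the results were seen; only the counts of splits were set before.

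A test of the difference between the imbibition responses passed for 22 genes in mkk3-1 and for 1 gene in mpk7_ko3. In mkk3-1 the largest of these differences from Col-0 among genes with a mean of at least 5 CPM were 3.73 for IRT3, 1.69 for AT3G19680, 1.33 for EXL5, 1.28 for AT4G32480 and 1.06 for MKK3 on the higher side. On the lower side they were -1.92 for ILA, -1.53 for RPL18AA, -1.19 for AT5G11420, -0.98 for APR3 and -0.95 for APR2. In mpk7_ko3 the gene was AT2G41650, at -1.98. Some of these calls rest on single libraries. AT4G32480 had an adjusted p = 0.0602 without Col-0 dry replicate 3 and 0.0572 and 0.0639 without replicate 1 of dry and imbibed mkk3-1. AT5G11420 had an adjusted p = 0.0625 and 0.0639 without the same mkk3-1 libraries and 0.0555 and 0.0573 without Col-0 imbibed replicates 2 and 3. EXL5 kept its call only without Col-0 imbibed replicate 3, mkk3-1 imbibed replicate 3 and mkk3-1 dry replicates 1 and 2 (adjusted p up to 0.121 without mkk3-1 dry replicate 3). AT3G19680 kept it only without Col-0 dry replicate 2, mkk3-1 dry replicate 2 and mkk3-1 imbibed replicate 3 (up to 0.0967 without mkk3-1 imbibed replicate 1). APR3 kept it only without Col-0 dry replicate 2, Col-0 imbibed replicate 2, mkk3-1 dry replicates 2 and 3 and mkk3-1 imbibed replicate 2 (up to 0.0967 without mkk3-1 imbibed replicate 1). Of 100 splits of the libraries, 6 gave as many genes as the real one for mkk3-1 (97 genes in a fit of the libraries compared, highest other 2470) and 9 for mpk7_ko3 (1 gene, highest other 2213). The splits with the most genes exchange genotype labels in imbibed seeds only, which turns a genotype effect present in both states into an interaction. They point to this structure of the samples and decide nothing about chance.

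The MKK3 transcript was low in dry but not in imbibed seeds labelled mkk3-1. Col-0 libraries under a wrong label are argued against: the 68 genes changed at least 2-fold in dry mkk3-1 moved by a median of 0.99 in the same direction in imbibed seeds (quartiles 0.69 and 1.62), and 64 of them had the same direction. The overlapping gene AT5G40450 had few reads, at 1.26 CPM (SD 0.451) in imbibed mkk3-1. MKK3 stood 6.12 CPM over the 5.66 CPM that the dry ratio predicts. This argues against reads spread over AT5G40450 as the source of the excess. It cannot decide on opposite-strand reads counted only for MKK3, because the strand setting is not stated. Transcripts of the mutant allele, which may accumulate after imbibition, stay open, because counts per gene do not resolve parts of a transcript.

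Ribosomal protein genes were lower (adjusted p = 0.0794 and 0.0785 with an estimated correlation) and heat shock genes higher in imbibed mkk3-1 and mpk7_ko3. A GC or length trend is argued against as the whole cause, since the weaker median was -0.35 for ribosomal and 0.83 for heat shock genes with the trend removed, and so is a single Col-0 library, with weakest medians of -0.37 and 0.72 when each was left out. Slower imbibition as the whole cause predicts no difference in dry seeds, but list means there were -0.24 (SE 0.0724) for ribosomal genes in mkk3-1 and 0.28 (SE 0.0950) for heat shock genes in mpk7_ko3. With an estimated correlation neither list shift passed camera (adjusted p = 0.272 and 0.405). By fry the ribosomal shift passed and the heat shock shift did not (adjusted p = 0.0247 and 0.0716). The argument is therefore weak for heat shock genes in mpk7_ko3. Slower imbibition could still add to the imbibed difference where the shift grew on imbibition. For heat shock genes the interaction median was 0.47 in both mutants (adjusted p = 0.136 and 0.0709 by camera with an estimated correlation). For ribosomal genes it was -0.11 in mkk3-1 (camera adjusted p = 0.00319, and 0.666 with an estimated correlation). In mpk7_ko3 it was 0.013 (camera adjusted p = 0.798), so the ribosomal shift there showed no growth on imbibition. Across genes, imbibed changes of mkk3-1 and mpk7_ko3 correlated with the imbibition response of the other mutant at -0.23 and -0.23. This is the direction that slower imbibition predicts, and the dry changes gave -0.076 and -0.18. Seed lots that differ in maturation, on which the labels are silent, cannot be separated from the genotypes.

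AT1G64795 and ILA, which overlap on opposite strands, were both higher in dry mkk3-1. A constant share of ILA reads counted for AT1G64795 is argued against by their ratio, 26.7 times higher in dry mkk3-1 than in dry Col-0. AT1G64795 lies wholly within the bounds of ILA. Counts per gene do not resolve parts of a transcript, so the ratio cannot decide on reads from only a part of ILA. AT1G64795 reads counted for ILA predict an ILA excess of 50.9 CPM in imbibed mkk3-1, where it was 0.284 CPM (SE 19.4). A separate change at this locus in the mkk3-1 line may be the source and was not tested. MKK3 itself lies on another chromosome. IRT3 and RPL18AA, also higher in dry mkk3-1, start at 22445299 and 10498351 on chromosome 1, as does AT1G64795 at 24082579. AT3G05945, lower in dry mkk3-1, lies on chromosome 3. With a single mkk3-1 line, changes that follow from MKK3 cannot be told from other changes in that line.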

How the results depend on the processing

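The removal of the GC and length trend, the fits without ribosomal RNA genes or without replicate 3 of mpk7_ko3, and the single libraries left out for gene lists were chosen after seeing the data; the other alternatives were not. The cause of the changes below was not tested except where a stricter threshold or fewer libraries lower a count by construction. Mean library totals were alike in all groups, but mean TMM factors ran from 0.810 in dry Col-0 to 1.23 in imbibed mkk3-1, so effective library sizes differed between the states. Simulated 1.5-fold differences in the interactions were recovered for 47.8% and 43.3% of genes, all with a mean of at least 5 CPM.

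The imbibition counts of Col-0, mkk3-1 and mpk7_ko3 stayed within 1.5 times except with at least 2-fold change (6758, 6339 and 6263). That threshold gave 69 and 203 genes in dry and imbibed mkk3-1, 57 and 113 in mpk7_ko3, 46 and 22 between the mutants, 9 for the mkk3-1 interaction, and overlaps of 15 and 53. An adjusted p below 0.01 gave 106, 639, 167 and 683 genes in the mutants in the same order, 28 and 19 between them and 5 for the mkk3-1 interaction. DESeq2 gave 649 and 775 genes in dry mkk3-1 and mpk7_ko3, 161 and 58 for the interactions, 610 and 226 between the mutants and a dry overlap of 205. A fit of only the libraries compared gave 230 and 2887 genes in dry and imbibed mkk3-1, 73 in dry mpk7_ko3, 97 for the mkk3-1 interaction and 29 between dry mutants. Without the low-count filter the interactions had 90 and 36 genes and the mutants differed in 504 and 233. The GC and length trend removed gave 44 and 4 for the interactions and 105 between imbibed mutants, and nuclear genes only gave 4 for the mpk7_ko3 interaction. Without replicate 3 of mpk7_ko3 in both states the mpk7_ko3 interaction had 7 genes and the mutants differed in 1095 dry and 454 imbibed.

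The replicate number as a block gave 369 and 1382 genes in dry and imbibed mkk3-1, 455 and 1669 in mpk7_ko3, and 25 and 2 for the interactions; nested in genotype it gave 63 and 22 for the interactions. Residuals of libraries with the same number had a median correlation of 0.0011 over 45 pairs, 12 of them above 0.1. For dry and imbibed libraries of the same genotype it was 0.098 over 9 pairs, from 0.0081 to 0.2785, 3 of them above 0.1, against -0.034 over 18 pairs with different numbers. Within Col-0, mkk3-1 and mpk7_ko3 the medians for the same number were 0.069, 0.099 and 0.203. The numbers were not taken to pair the libraries in the main fit. These values go with a weak pairing within a genotype, which the imbibition and interaction tests of the main fit leave out.

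With each library left out in turn, imbibition counts ran from 12721 to 12819 in Col-0, 12369 to 12471 in mkk3-1 and 12332 to 12578 in mpk7_ko3. They ran from 130 to 409 in dry and 756 to 1003 in imbibed mkk3-1, and from 146 to 575 in dry and 887 to 1386 in imbibed mpk7_ko3. The interactions ran from 5 to 78 and 1 to 19, the differences between the mutants from 33 to 882 in dry and 18 to 198 in imbibed seeds, and the overlaps from 30 to 144 and 405 to 678.

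Library totals reversed the imbibition direction of MKK3 (0.22), MPK7 (0.37) and CYP707A2 (0.38) in Col-0 and of MPK7 in mkk3-1 (0.47) and mpk7_ko3 (0.37). These scalings differ because imbibed seeds had higher TMM factors than dry ones, 1.23 against 0.810 in Col-0.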

Other observations

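The counts of splits below were set before the results were seen, and no other test was run for this part.

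Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. For imbibition in Col-0, mkk3-1 and mpk7_ko3, 1 split, the real one, gave as many genes as the real value of 13108, 12718 and 11707 in fits of the libraries compared, and the highest other gave 0 by edgeR. In dry and imbibed mkk3-1 the real split gave 230 and 2887 genes and the highest other 1 in each. In imbibed mpk7_ko3 the real split gave 2039 genes and the highest other 0 by edgeR. In dry mpk7_ko3, 2 splits gave at least the real 73 genes, the other 175; it set replicates 2 and 3 of Col-0 with replicate 3 of mpk7_ko3 against the rest, which points to a structure of the samples beside genotype. Between the dry mutants 2 splits gave at least the real 29 genes, the other 298, which exchanged replicate 2 of mkk3-1 with replicate 3 of mpk7_ko3. Between the imbibed mutants the real split gave 80 genes and the highest other 58, which exchanged the libraries with the same numbers.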
